A study of Mus musculus with 16 samples.

How the data were processed

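Total RNA from the colon of 16 mice was labelled and hybridised to 16 Affymetrix arrays, 1 array per mouse. The labels give 2 ug of RNA per mouse and 4 groups: germ-free (GF, 2 arrays), HC (4 arrays), CD (5 arrays) and UC (5 arrays). Per the submitters' processing notes, the authors summarised the probe sets with RMA in Affymetrix Expression Console. RMA corrects the background, applies quantile normalisation and summarises the probes of a probe set by median polish. The versions of both, the probe set library and the genome build are not given in the sources used here. The deposited values are probe set intensity on a linear scale: all lie above 0 and the medians per array lie between 4.53 and 5.27. The deposited intensity was converted to log2 intensity before every computation, with no further normalisation. RMA gives log2 values, and how the submitters returned them to a linear scale is not given in the sources used here. Every log2 level and fold change therefore assumes that 2 was raised to the RMA value and nothing else was done.

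Of 41345 probe sets, 23521 carried 1 gene symbol, 1814 carried several and 16010 carried none in the annotation used here. Control probe sets could not be told apart from the others without a symbol. The 23521 probe sets cover 22180 genes, 1082 of them with several probe sets. For those genes the probe set with the highest mean was used. No filter on dim genes was applied. The number of arrays limits the precision, most of all for the 2 GF arrays.

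Groups were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means, all 16 arrays in 1 fit, two-sided tests). A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over 22180 genes). There were 8 comparisons: 6 between pairs of groups, the mean of CD and UC against HC, and the mean of HC, CD and UC against GF. Lists of genes for cell types, immune pathways, epithelial functions and metabolism were written from general knowledge. There were 44 lists with 1312 genes, of which 1198 were measured. A list of sex-linked genes served only to describe the arrays, and the other 43 were tested with camera at a preset correlation between genes of 0.01, adjusted over the 43 lists. camera asks whether a list's genes are shifted relative to all other genes. Each list was also tested with a correlation estimated from the arrays and with fry. Within a list, members were also counted as passing when adjusted over the list alone. The groups, comparisons, lists, thresholds and the alternatives listed first below were fixed before the data were examined.

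Genes were named by a rule. In each comparison of a pair of groups it takes, of the called genes whose arrays do not overlap, up to 8 with the highest and 8 with the lowest log2 fold change. For the comparisons with a mean of groups it takes 5 and 5. Where none passed, it takes the 5 genes with the smallest unadjusted p in each direction, stated as not having passed. Predicted genes, microRNAs, small nucleolar RNAs and olfactory and vomeronasal receptors were counted but not named. For a list, up to 4 members with the smallest p are named. Always covered were Reg3b, Reg3g, Retnlb, Saa1, Saa3, Fut2, Angptl4, Nos2, Duox2, Lcn2, Il1b, Tnf, Il17a, Il22, Ifng, Il10, Foxp3, Muc2, Igha and Cxcl9. Saa1 and Igha had no probe set with 1 symbol, which leaves 18. Genes chosen after their values were seen are stated as such.

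The method was tested on simulated data with 22180 genes and the same groups, each gene drawn independently of the others. For each pair of groups 67, 67 and 66 genes were changed at once, by 1, 2 and 3 on the log2 scale. For a log2 change of 1, between 47.8% and 73.1% of changed genes were called across the 6 pairs of groups, and for a change of 2 between 82.1% and 94%. Of unchanged genes, 0.027% to 0.064% were called. A shifted list was called with the preset and with the estimated correlation. With no correlation between genes in the simulated data, these rates do not show how often genes or lists are called by chance in the real arrays. Where fewer genes truly change, the adjusted threshold is stricter and a smaller share of changes would be called.

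The first set of alternatives left out the dimmest 25% or 50% of genes, averaged the probe sets of a gene, or tested every probe set. Others used a trended and robust variance, only the groups compared, the replicate number as a block, cyclic loess normalisation, array weights, a fold change of at least 1.5, and each array left out in turn. Added after seeing the data were a term for sex read from Xist, only the arrays with low or only those with high Xist, and the log2 level of Hoxb13 as a covariate, alone and with sex. Also added were fits without the 4 arrays with the narrowest spread of values, and with the level of the B cell genes Cd79a and Ms4a1 as a covariate. For comparisons of groups with at least 3 arrays each, 100 splits of the same arrays into groups of the same sizes were refitted. Overlaps between comparisons that share a group were set against 100 draws in which the differences between group means were removed and the residuals shuffled over the arrays. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.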

Results

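Gene expression was measured in the colon of 16 mice, with 1 array per mouse. GF stands for 2 germ-free wild-type mice. The others had carried a human gut microbiota for 2 weeks and are labelled HC (4 mice), CD (5 mice) and UC (5 mice). The labels do not spell these letters out. From knowledge of the study they stand for healthy controls, Crohn's disease and ulcerative colitis. The tissue was a piece of 2 to 3 mm from the middle of the colon of mice aged 6 to 10 weeks. Strain, sex, the number of human donors, cages, litters and the time of day of collection are not in the labels used here, so every p-value measures only the spread between these mice. Levels are log2 intensity, with the SD after a group mean and the SE after a log2 fold change. Adjusted p-values of genes come from limma over 22180 genes and those of gene lists from camera over 43 lists, both with the Benjamini-Hochberg method. The main genes are Wdfy1 (probe set 17224745), Erdr1 (17546774), Gpr161 (17218942), Alas1 (17530653), Zfp429 (17293961) and Sprr1a (17407412). Members of lists given as examples did not pass over all 22180 genes unless this is stated.

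Xist, the RNA that silences an X chromosome in female cells, lay at 8.86 to 9.76 in GF 1, GF 2, HC 2, HC 3, UC 3, UC 4 and UC 5. In all 5 CD arrays and in HC 1, HC 4, UC 1 and UC 2 it lay at 1.40 to 3.06, and the Y-linked gene Eif2s3y lay there at 6.20 to 7.09. All GF arrays were thus high in Xist and all CD arrays low, and these groups differ in sex as read from these genes. Hoxb13, a gene of the distal colon, was low in UC 1 (1.08), CD 2 (1.26) and CD 1 (3.07) and lay at 5.86 to 7.93 in the other 13. The spread of values within an array (interquartile range of log2 intensity) was 2.96 to 3.36 in HC 2, UC 3, UC 4 and UC 5, here called the 4 narrow arrays, and 3.49 to 3.55 in the other 12. Ms4a1, a B cell gene of lymphoid follicles, was at 6.02 in CD 3 and 5.67 in CD 5 against 1.60 to 4.28 elsewhere.

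**Figure D1:**
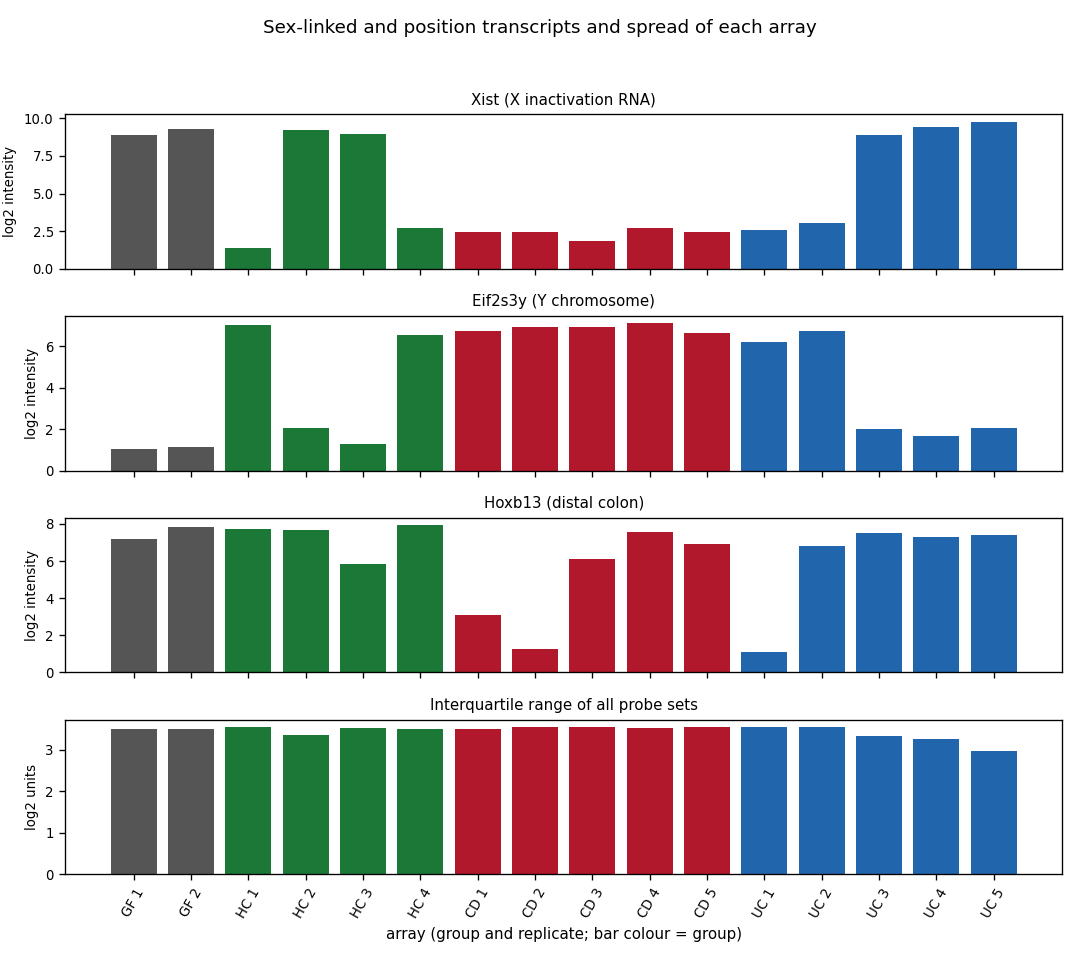
Xist, Eif2s3y and Hoxb13 (log2 intensity) and the interquartile range of log2 intensity for each of the 16 arrays, coloured by group. Xist is at 8.86 or above in 7 arrays, and the interquartile range is 3.36 or below in 4.

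HC mice differed from GF mice in 2 genes. Wdfy1, an endosomal adaptor of Toll-like receptor signalling, was at 5.34 ± 0.37 in HC and 3.77 ± 0.13 in GF, a rise of 1.57 ± 0.23 on the log2 scale (2.97-fold) that showed in 4 of 4 HC arrays. Erdr1, a secreted factor that restrains cell migration and survival, fell from 9.20 ± 0.03 to 6.50 ± 0.73, a log2 fold change of -2.69 ± 0.38, with every HC array below both GF arrays. Both had a limma adjusted p of 0.0459, and 734 genes had an unadjusted p under 0.05. The arrays of the groups did not overlap for 15.27% of genes, against 13.33% by chance. Neither call held without GF 1 (adjusted p of 0.409 for both), HC 1 (0.143) or HC 2 (0.2), Wdfy1 was lost without GF 2 (0.448) or HC 3 (0.201), and Erdr1 was lost without GF 2 (0.533) or HC 4 (0.0884). The count was also 0 with the probe sets of a gene averaged, with every probe set tested, with a trended robust variance, with the replicate number as a block and with only the GF and HC arrays in the fit. Of the alternatives added later, a term for sex, Hoxb13, both together, high Xist alone and leaving out the 4 narrow arrays gave 0 as well. Over 20 alternatives the log2 fold change ran from 1.48 to 1.75 for Wdfy1 and from -3.05 to -2.13 for Erdr1, and the adjusted p from 0.00482 to 0.916 and from 0.000712 to 1. Of the 18 genes covered in every comparison, including Reg3g, Il1b and Cxcl9, none passed here: limma gave 0 of them an unadjusted p under 0.05.

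The cell cycle list held 38 of 49 members with higher values in HC than in GF, with a median log2 fold change of 0.51 (camera adjusted p = 1.23e-08; adjusted p = 0.955 with an estimated correlation). Mki67, a marker of dividing cells, had a log2 fold change of 0.85 ± 0.37 and Aurkb, a mitotic kinase, 0.97 ± 0.44. Of the members, 3 had an unadjusted p under 0.05 and limma called 0 adjusted over the list alone. With a term for sex, which rests on the HC and UC arrays and in UC cannot be told apart from narrow spread, the median was 0.12 and the call was lost, whereas among the arrays with high Xist alone it was 0.44 and without the 4 narrow arrays 0.51, and the call held. Genes of neurons and glia of the gut wall were lower in 26 of 31 members (median -0.54, camera adjusted p = 0.000447; adjusted p = 0.955 with an estimated correlation). Among them were Nos1, the nitric oxide synthase of inhibitory motor neurons (-0.77 ± 0.31), and Elavl4 (-0.42 ± 0.19). This median was -0.30 without HC 2 or without the 4 narrow arrays and -0.90 with the term for sex, with the call held. Smooth muscle genes varied beside them, from a mean level of -0.59 in HC 4 to 0.75 in HC 3 against 0.25 and 0.16 in the GF arrays. Glycolysis and hypoxia genes were lower in 22 of 26 members, such as Bnip3 (-1.18 ± 0.46) and the lactate exporter Slc16a3 (-0.68 ± 0.30), with a median of -0.28 (camera adjusted p = 5.33e-05; adjusted p = 0.864 with an estimated correlation). The clock list was lower in 13 of 19 members (median -0.64, camera adjusted p = 0.00227; adjusted p = 0.223 with an estimated correlation). Of these genes 3 fell and 1 rose adjusted over the list alone, among them Ciart (-2.06 ± 0.49), Tef (-1.09 ± 0.26) and Npas2 (1.61 ± 0.47). The list lost its call with the dimmest 50% of genes left out (0.0552), and without GF 2 its median was -0.39.

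Cholesterol and lipid synthesis genes were lower in 25 of 33 members in HC than in GF, with Insig1 at -0.69 ± 0.22 and Sqle at -0.78 ± 0.30. The median was -0.17 (camera adjusted p = 0.00901; adjusted p = 0.955 with an estimated correlation). Oxidative phosphorylation genes were lower in 36 of 43 members (median -0.12, camera adjusted p = 0.00812; adjusted p = 0.864 with an estimated correlation). Both calls were lost without GF 2 or HC 3, with camera adjusted p up to 0.613 and 0.203, and the cholesterol median ran from -0.06 without GF 2 to -0.34 without GF 1. The cholesterol call was also lost among arrays with high Xist alone, and the oxidative phosphorylation median was -0.20 with the term for sex. Tight junction genes were higher in 19 of 30 members, such as Tjp3 (0.50 ± 0.15), and this call was lost without GF 1 or HC 1 (up to 0.287), among arrays with high Xist alone and without the 4 narrow arrays. Their median was 0.10 (camera adjusted p = 0.00901; adjusted p = 0.864 with an estimated correlation). Camera called 11 of 43 lists in all, and 7 without GF 2. With an estimated correlation and with fry the count was 0, with adjusted p of 0.223 to 0.981 for the 11.

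CD mice differed from GF mice in 1 gene, Gpr161. This receptor of the primary cilium, which restrains hedgehog signalling, fell from 2.78 ± 0.08 in GF to 1.44 ± 0.13 in CD. Its values lie among the dimmest 50% of genes, near those of Ifng (1.54 in CD) and Il17a (1.45 in CD), and whether they stand above background was not measured. The log2 fold change was -1.34 ± 0.17 with a limma adjusted p of 0.0213, and all 5 CD arrays lay below both GF arrays. At an unadjusted p under 0.05 there were 1353 genes, and 13.93% of genes had arrays that did not overlap, against 9.52% by chance. Gpr161 was lost without GF 1 (adjusted p of 0.306), GF 2 (0.295), CD 2 (0.0819), CD 3 (0.0798) or CD 5 (0.0583), and the count was 0 with every probe set tested or with the replicate number as a block, 5 without CD 4, 6 without the 4 narrow arrays, 21 with only the GF and CD arrays in the fit and 40 with array weights. Over 19 alternatives its log2 fold change ran from -1.47 to -1.27 and its adjusted p from 0.000612 to 0.306. Of the 18 genes covered throughout, Il1b had an unadjusted p under 0.05 (0.98 ± 0.45, limma adjusted p = 0.797) and 0 passed. All GF arrays were high and all CD arrays low in Xist. With a term for sex, which rests on the HC and UC arrays, 0 genes were called, with Gpr161 at -1.44 (limma adjusted p = 0.128).

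All 49 cell cycle genes had higher values in CD than in GF, with a median of 0.95 (camera adjusted p = 4.36e-34; adjusted p = 0.238 with an estimated correlation). Adjusted over the list alone, 25 rose and 24 did not pass. Examples are Birc5, an inhibitor of cell death in mitosis (1.32 ± 0.35), the cyclin Ccna2 (1.35 ± 0.33) and Mki67 (1.23 ± 0.36). With the term for sex the median was 0.23. Macrophage and dendritic cell genes were higher in 33 of 35 members, 7 of them at an unadjusted p under 0.05, with a median of 0.74 (camera adjusted p = 1.23e-12; adjusted p = 0.238 with an estimated correlation). Cd209a, a receptor of tissue macrophages and dendritic cells, was at 1.35 ± 0.42 and Ccr2, the receptor that draws monocytes into tissue, at 1.19 ± 0.50. The term for sex brought this median to 0.41. B cell and follicle genes were higher in 26 of 27 members, led by the follicle chemokine Cxcl13 (1.90 ± 0.74) and Ltb (1.28 ± 0.54). Their median was 0.91 (camera adjusted p = 5.84e-09; adjusted p = 0.306 with an estimated correlation). Plasma cell genes were higher in 14 of 18 members, with the antibody joining chain Jchain at 2.55 ± 0.86 and a median of 0.79 (camera adjusted p = 2.63e-06; adjusted p = 0.238 with an estimated correlation). The mean level of the B cell list stood at 2.06 in CD 3 and 1.78 in CD 5, and at 0.39 or lower in the other 14 arrays. Without CD 3 the B cell median was 0.48 and the plasma cell median 0.50, without CD 5 the B cell median was 0.56, and the calls held.

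T cell genes were higher in CD than in GF in 23 of 26 members, such as the cytotoxic granule genes Gzma (2.84 ± 1.12) and Gzmb (2.09 ± 0.79). Their median was 0.45 (camera adjusted p = 4.82e-06; adjusted p = 0.293 with an estimated correlation), and 0.25 without CD 3. MHC class II genes were higher in 12 of 17 members, with H2-Ab1 at 1.33 ± 0.51 and a median of 0.77 (camera adjusted p = 0.000155; adjusted p = 0.276 with an estimated correlation). With the term for sex that call was lost, at a median of 0.44, and the median was 0.45 without CD 3 and 0.44 without CD 5 with the call held. Antimicrobial genes were higher in 24 of 31 members (median 0.28, camera adjusted p = 0.000301; adjusted p = 0.238 with an estimated correlation), with the lectin Reg3g at 3.20 ± 1.60 and the lysozyme Lyz1 at 2.06 ± 0.93. Without CD 3 the antimicrobial median was 0.10, with the call held. Cholesterol and lipid synthesis genes were lower in 27 of 33 members (median -0.44, camera adjusted p = 2.31e-07; adjusted p = 0.238 with an estimated correlation). 4 of them fell adjusted over the list alone, namely Insig1, which restrains cholesterol synthesis and is switched on by SREBP (-1.15 ± 0.21), Hsd17b7 (-0.76 ± 0.21), Sqle (-0.95 ± 0.29) and Srebf1 (-0.58 ± 0.17). Without GF 2 the median was -0.27. Nutrient transport genes were lower in 31 of 41 members (median -0.38, camera adjusted p = 0.000416; adjusted p = 0.26 with an estimated correlation). 2 fell adjusted over the list alone, the amino acid transporters Slc6a19 (-1.61 ± 0.37) and Slc7a8 (-1.78 ± 0.45). Slc6a19 lay at 4.44 in GF 1 and 2.34 in GF 2, and its log2 fold change was -0.56 without GF 1 and -2.66 without GF 2. The mean level of the transport list was 0.26 in CD 4, near the GF arrays (0.30 and 0.42), and -0.40 to -0.26 in the other CD arrays. Clock genes were lower in 14 of 19 members, and adjusted over the list alone 10 fell and 2 rose, with Ciart at -2.76 ± 0.47, Per3 at -1.77 ± 0.33 and Tef at -1.41 ± 0.25. Their median was -0.80 (camera adjusted p = 1.05e-06; adjusted p = 0.0167 with an estimated correlation), and the call held in each of 15 alternatives. Camera called 25 of 43 lists, against 1 with an estimated correlation and 1 with fry, the clock list in both.

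UC mice differed from GF mice in 3 genes. Wdfy1 rose by 1.77 ± 0.22 (3.42-fold, limma adjusted p = 0.0136), and Erdr1 had a log2 fold change of -2.79 ± 0.37 (limma adjusted p = 0.0158). Gpr161 was at 1.59 ± 0.28 in UC, a log2 fold change of -1.19 ± 0.17 (limma adjusted p = 0.0298). For each of the 3 genes, all 5 UC arrays lay on the same side of both GF arrays. At an unadjusted p under 0.05 there were 1375 genes, and the arrays did not overlap for 10.75%, against 9.52% by chance. Without GF 1 or GF 2 these 3 calls were lost (adjusted p of 0.184 to 0.286 and 0.213 to 0.633). Without UC 2, Erdr1 (0.0526) and Gpr161 (0.0921) were lost, and without UC 1 the count was 5. It was 0 with the replicate number as a block, with only the GF and UC arrays in the fit, among arrays with high Xist and without the 4 narrow arrays. Over the alternatives the log2 fold changes ran from 1.66 to 1.91 for Wdfy1, -2.96 to -2.20 for Erdr1 and -1.28 to -1.07 for Gpr161, and the adjusted p from 0.00116 to 0.213 for Wdfy1, to 0.286 for Erdr1 and to 0.659 for Gpr161. Of the 18 genes covered throughout, Duox2, which makes hydrogen peroxide at the epithelial surface, had an unadjusted p under 0.05 (1.56 ± 0.70, limma adjusted p = 0.799) and 0 passed.

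Type I interferon response genes had higher values in UC than in GF in 27 of 31 members, such as Ifit1, which binds viral RNA (1.88 ± 0.68), Irf7 (1.46 ± 0.47) and Zbp1 (1.81 ± 0.64). The median was 0.53 (camera adjusted p = 3.05e-06; adjusted p = 0.665 with an estimated correlation), 3 members had an unadjusted p under 0.05, and limma called 0 adjusted over the list alone. The list stood at 0.38, 0.51 and 0.96 in UC 3, UC 4 and UC 5 and at 0.58 in HC 2, which are the 4 narrow arrays, and without these the median was 0.03 and the call was lost. It was 0.31 without UC 5, 0.81 with the term for sex and 0.85 among arrays with high Xist. Interferon-gamma response genes were higher in 21 of 29 members, with Socs1 at 0.72 ± 0.29 and a median of 0.24 (camera adjusted p = 0.00633; adjusted p = 0.85 with an estimated correlation). That call was lost without GF 2 (median 0.10) or UC 2 (0.11), with a camera adjusted p up to 0.551, and with the replicate number as a block (0.16). The median was 0.57 without GF 1, 0.53 without UC 1, 0.39 without UC 3, 0.41 without the 4 narrow arrays and 0.53 with Hoxb13 in the model. Clock genes were lower in 13 of 19 members (median -0.62, camera adjusted p = 0.004; adjusted p = 0.317 with an estimated correlation). Of these, 9 fell and 4 rose adjusted over the list alone, among them Per1 (-1.65 ± 0.28), Dbp (-2.66 ± 0.60) and Npas2 (2.07 ± 0.45). With the dimmest 50% of genes left out the call was lost (0.147).

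Oxidative phosphorylation genes were lower in UC than in GF in 30 of 43 members, with Idh3a of the citric acid cycle at -0.75 ± 0.20. The median was -0.18 (camera adjusted p = 0.00099; adjusted p = 0.665 with an estimated correlation), and -0.11 without the 4 narrow arrays. Glycolysis genes were lower in 22 of 26 members, with Pdk1 at -0.80 ± 0.24 and a median of -0.32 (camera adjusted p = 0.00103; adjusted p = 0.665 with an estimated correlation), a call lost with the dimmest 50% of genes left out (0.0549) and among arrays with high Xist alone (0.106, median -0.20). Cholesterol synthesis genes were lower in 26 of 33 members, with Acss2 at -0.80 ± 0.27 and a median of -0.24 (camera adjusted p = 0.00099; adjusted p = 0.665 with an estimated correlation), a call lost without GF 2 (0.156, median -0.16) and with the dimmest 50% of genes left out (0.0549). Fibroblast genes were lower in 30 of 37 members (median -0.40) and endothelial genes in 26 of 29 (median -0.27), with Cdh5 of vessel junctions at -1.05 ± 0.39. Both had a camera adjusted p of 0.0105 and an adjusted p = 0.85 with an estimated correlation. Without the 4 narrow arrays both medians were above 0, at 0.27 and 0.13, and both calls were lost without GF 1 or UC 5 and the fibroblast call also without UC 3 (up to 0.254, and 0.685 for endothelial genes). The fibroblast median was -0.22 without UC 5, and the endothelial median was -0.06 without GF 1, -0.15 without UC 5 and -0.56 without GF 2. Both calls were also lost with the dimmest 50% of genes left out and with the replicate number as a block (0.59 and 0.272). Smooth muscle genes moved with them, at 0.70 and 0.54 in UC 1 and UC 2 and at -0.25, -0.14 and -0.94 in UC 3, UC 4 and UC 5. Camera called 9 of 43 lists, 17 without UC 1, 0 with an estimated correlation and 2 with fry.

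The 3 colonised groups together differed from GF in 1 gene, Gpr161, with a log2 fold change of -1.16 ± 0.16 (limma adjusted p = 0.0366). Every colonised array, 14 of 14, lay below both GF arrays. At an unadjusted p under 0.05 there were 970 genes, and 1.91% had arrays that did not overlap, against 1.67% by chance. The count was 0 without GF 1, HC 2, UC 2, CD 1, CD 2, CD 3 or CD 5, 2 without HC 1, HC 3, UC 1 or UC 4, 3 without CD 4, 4 without HC 4 and 28 with array weights. It was also 0 with every probe set tested, with a trended robust variance and with the replicate number as a block. Gpr161 was not tested with the dimmest 50% of genes left out, where the count was 0, and with the term for sex it was at -1.23 without passing (0.0746). Over 27 alternatives its log2 fold change ran from -1.24 to -1.08 and its adjusted p from 0.00053 to 0.568. None of the 18 genes covered throughout had an unadjusted p under 0.05 with limma.

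Clock genes also held their call with an estimated correlation. Of 19 members 13 were lower in the colonised mice, with a median of -0.69 (camera adjusted p = 1.88e-05; adjusted p = 0.0374 with an estimated correlation; fry adjusted p = 0.00725). The call held in each of 24 alternatives. Adjusted over the list alone, 10 clock genes fell and 3 rose. Ciart, a repressor of the clock, had a log2 fold change of -2.48 ± 0.43, and the output regulators Dbp and Tef had -2.30 ± 0.54 and -1.17 ± 0.23. Per1, of the repressing arm, had -1.23 ± 0.26. Dbp was at 5.73 and 6.01 in GF, at 2.58 to 4.08 in CD and UC, and at 2.98 to 5.92 in HC. Arntl and Npas2, the activating arm that peaks opposite to Dbp, were lower in both GF arrays than in every colonised array.

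**Figure D2:**
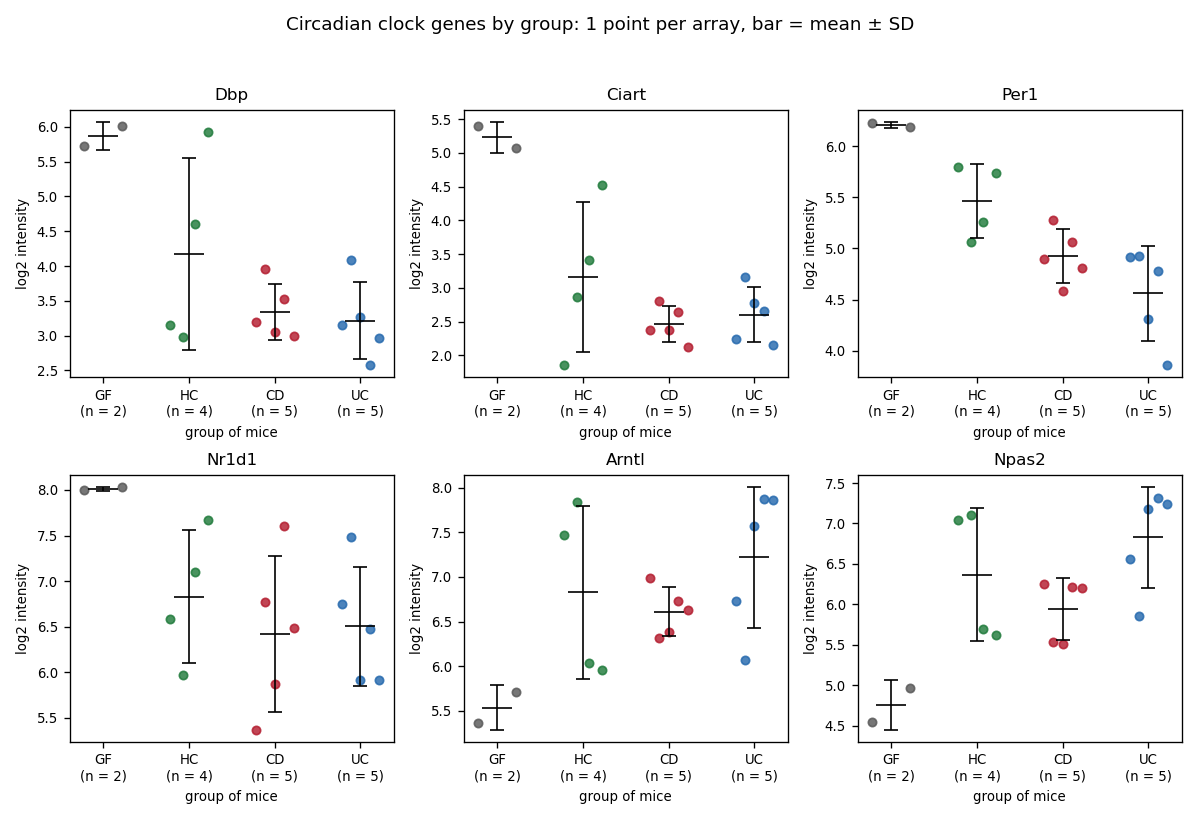
Log2 intensity of the clock genes Dbp, Ciart, Per1, Nr1d1, Arntl and Npas2 per array by group, with mean and SD. Dbp is at 5.73 and 6.01 in the GF arrays, while Npas2 is at 4.54 and 4.97 there and at 5.51 or above in the colonised arrays.

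Cell cycle genes had higher values in the mean of the 3 colonised groups in 42 of 49 members, with a median of 0.50 (camera adjusted p = 2.3e-14; adjusted p = 0.49 with an estimated correlation). UC against GF was not called (median 0.11, camera adjusted p = 0.155), but the UC arrays were split. The narrow arrays UC 4 (-0.90) and UC 5 (-1.10) lay below both GF arrays (-0.33 and -0.46). UC 1 (0.22), UC 2 (0.42) and the narrow array UC 3 (-0.22) lay above them. Of the members, 12 had an unadjusted p under 0.05 and limma called 0 adjusted over the list alone. With a term for sex the median was 0.04 and the call was lost, while without the 4 narrow arrays it was 0.77. Glycolysis genes were lower in 24 of 26 members, with Bnip3 at -1.21 ± 0.40 and a median of -0.29 (camera adjusted p = 1.01e-05; adjusted p = 0.49 with an estimated correlation). Cholesterol synthesis genes were lower in 27 of 33, with Insig1 at -0.68 ± 0.19 and a median of -0.32 (camera adjusted p = 8.56e-06; adjusted p = 0.49 with an estimated correlation). Insig1 was higher in every GF and UC array than in every HC and CD array, so this example rests mainly on HC and CD. Nutrient transport genes were lower in 31 of 41 (median -0.28, camera adjusted p = 0.00395; adjusted p = 0.49 with an estimated correlation). The transport list was called against GF in CD but not in HC or UC, and the plasma cell list below in HC and CD but not in UC. The amino acid transporter Slc6a19 fell adjusted over the list alone (-1.67 ± 0.33), but its log2 fold change was -0.62 without GF 1 and -2.72 without GF 2. The cholesterol and transport calls were lost without GF 2, each with a camera adjusted p of 0.0524, and the transport call with the dimmest 50% of genes left out (0.0704). Plasma cell genes were higher in 16 of 18 members, with Jchain at 1.82 ± 0.77 and a median of 0.31 (camera adjusted p = 0.00159; adjusted p = 0.49 with an estimated correlation), a call lost without GF 2 (0.0642, median 0.08) and with the term for sex (0.0783). The plasma cell median was 0.18 without HC 3, 0.18 without CD 3 and 0.49 without the 4 narrow arrays. Camera called 20 of 43 lists, and 10 without GF 2.

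Erdr1 and Wdfy1 were called in HC and in UC against GF, where 0.05 shared genes came up on average in shuffled data. Gpr161 was shared by CD and UC against GF, where shuffled data gave 0.04. These comparisons share the GF arrays. Across genes, which are not independent replicates, the correlation of log2 fold changes was 0.66 for HC and UC and 0.53 for CD and UC. Shuffled data gave 0.66 and 0.71.

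CD mice differed from HC mice in 2 genes, the same 2 that separated HC and UC from GF. Wdfy1 was at 3.55 ± 0.17 in CD and 5.34 ± 0.37 in HC, a log2 fold change of -1.79 ± 0.18 (limma adjusted p = 0.000654). Erdr1 was at 8.99 ± 0.26 in CD against 6.50 ± 0.73, a rise of 2.49 ± 0.30 on the log2 scale (5.61-fold, limma adjusted p = 0.00417). For both genes none of the 5 CD arrays overlapped the 4 HC arrays, and both calls held with each array left out. In GF and CD together Wdfy1 lay at 3.38 to 3.87, and in HC and UC at 4.80 to 6.00. Erdr1 lay at 8.70 to 9.32 and at 5.79 to 7.59, while in its second probe set the arrays overlapped, at 7.31 to 8.24 and 5.84 to 7.55. Wdfy1 lost its call among the arrays with low Xist alone (-1.61, adjusted p of 0.117). Erdr1 lost it without the 4 narrow arrays (2.31, adjusted p of 0.0511) and with its 2 probe sets averaged (1.92, adjusted p of 0.073), with only the CD and HC arrays in the fit (0.085), with sex and Hoxb13 together (2.53, adjusted p of 0.0591), and with the replicate number as a block (2.52, adjusted p of 0.0507). Over 23 alternatives the adjusted p ran from 7.83e-05 to 0.117 for Wdfy1 and from 9.44e-05 to 0.085 for Erdr1. At an unadjusted p under 0.05 there were 1651 genes, and the arrays did not overlap for 2.84%, against 1.59% by chance.

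**Figure D3:**
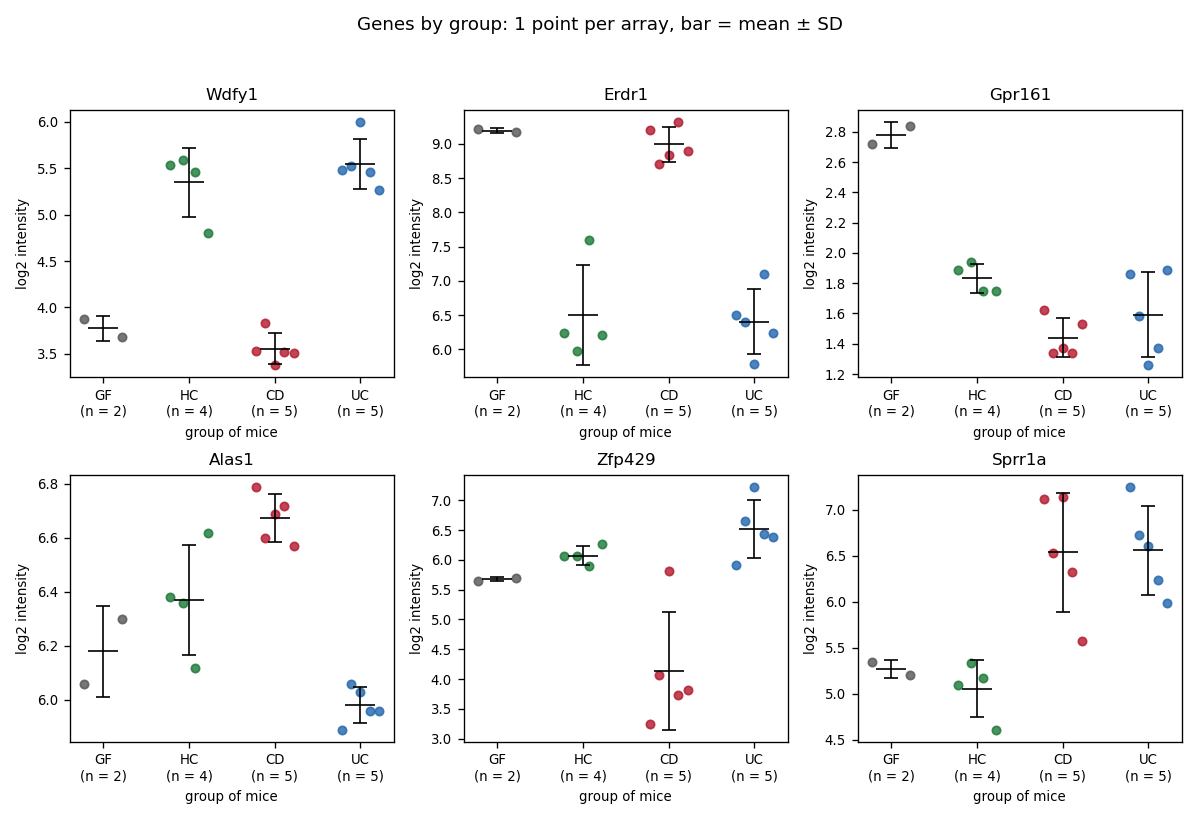
Log2 intensity of Wdfy1, Erdr1, Gpr161, Alas1, Zfp429 and Sprr1a per array by group, with mean and SD. Wdfy1 lies at 3.38 to 3.87 in GF and CD and at 4.80 to 6.00 in HC and UC, and Zfp429 in CD is at 5.81 in CD 3 and at 3.24 to 4.06 in the other 4 arrays.

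Of the 18 genes covered throughout, 4 had higher values in CD than in HC at an unadjusted p under 0.05, and limma passed 0, the smallest adjusted p being 0.554. Retnlb, a bactericidal protein of goblet cells, had a log2 fold change of 3.51 ± 1.14 (limma adjusted p = 0.554) and lay at 5.69 to 10.41 in CD and at 2.99 to 8.66 in HC. Cxcl9, a T cell chemokine driven by interferon-gamma, had 2.17 ± 0.75 (limma adjusted p = 0.562), and the fucosyltransferase Fut2 and Il1b had 0.57 ± 0.23 and 0.83 ± 0.36 (limma adjusted p = 0.649 each). Reg3g was at 5.89 ± 2.77 in CD and 3.82 ± 1.34 in HC, and Saa3 at 5.85 ± 2.88 and 3.42 ± 0.75. Ifng (1.54 against 1.37), Il17a (1.45 against 1.54), Il22 (0.60 against 0.42) and Il10 (1.40 against 1.47) stayed near the low end of the scale in both groups.

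B cell and lymphoid follicle genes had higher values in CD than in HC in 26 of 27 members, with a median of 1.15 (camera adjusted p = 5.04e-15; adjusted p = 0.308 with an estimated correlation). Adjusted over the list alone 1 rose and 26 did not pass. Examples are Ltb, which builds follicles (1.64 ± 0.43), Cxcl13 (1.86 ± 0.59) and Ccr7 (0.92 ± 0.34). Without CD 3, which with CD 5 carried the follicle genes, the median was 0.76, without CD 5 it was 0.80, and the call held. Macrophage and dendritic cell genes were higher in 30 of 35 members, 20 at an unadjusted p under 0.05 and 2 adjusted over the list alone, with Csf2rb at 1.38 ± 0.36, Flt3 at 1.16 ± 0.32 and Tyrobp at 1.17 ± 0.40. Their median was 0.86 (camera adjusted p = 3.46e-14; adjusted p = 0.308 with an estimated correlation), and their mean level was 1.03 in CD 3, 0.80 in CD 5, 0.72 in CD 2 and 0.51 in HC 3. T cell genes were higher in 23 of 26 members (median 0.55, camera adjusted p = 1.15e-11; adjusted p = 0.302 with an estimated correlation). 3 of these rose adjusted over the list alone, with Cd7 at 1.33 ± 0.34, Cd3d of the T cell receptor at 1.30 ± 0.37 and Ccl5 at 1.81 ± 0.50. This list stood at 1.13 in CD 3 and 0.62 in CD 5. Th1 genes were higher in 16 of 17 members, of which 3 rose adjusted over the list alone, namely Stat4, which carries the interleukin-12 signal (1.72 ± 0.36), Il18rap (0.79 ± 0.20) and Il12rb2 (0.46 ± 0.15). Their median was 0.29 (camera adjusted p = 5.04e-06; adjusted p = 0.191 with an estimated correlation), and 0.19 without CD 3, a move of over 1.5 times. Stat4, Il18rap and Il12rb2 lie among the dimmest 50% of genes, at brightness percentiles of 48, 31 and 41. Whether their levels stand above background was not measured. The Th1 list was not tested with the dimmest 50% of genes left out.

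Interferon-gamma response genes were higher in CD than in HC in 24 of 29 members, with Ido1, which degrades tryptophan, at 1.45 ± 0.54. The median was 0.47 (camera adjusted p = 4.79e-06; adjusted p = 0.399 with an estimated correlation), 0.25 without CD 3 and 0.73 with Hoxb13 in the model. MHC class II genes were higher in 12 of 17 members, such as H2-Aa (1.12 ± 0.41) and their master regulator Ciita (0.96 ± 0.36). Their median was 0.76 (camera adjusted p = 0.000237; adjusted p = 0.351 with an estimated correlation), 0.44 without CD 3 and 0.42 without CD 5. Adding the level of the B cell genes Cd79a and Ms4a1 to the model brought it to 0.04 with the call lost. Plasma cell genes were higher in 14 of 18 members, with Slamf7 at 1.51 ± 0.53 and a median of 0.59 (camera adjusted p = 0.00262; adjusted p = 0.399 with an estimated correlation). With the B cell level in the model this median was -0.13, without CD 3 it was 0.32, and the call was lost with the dimmest 50% of genes left out (0.0535). Cytokines and chemokines were higher in 29 of 38 members, with the monocyte chemokine Ccl8 at 2.55 ± 0.79 and a median of 0.26 (camera adjusted p = 2.84e-05; adjusted p = 0.308 with an estimated correlation). This call was lost with the B cell level in the model (median 0.11), and without CD 2 the median was 0.40. Antimicrobial genes were higher in 21 of 31 members (median 0.16, camera adjusted p = 0.00975; adjusted p = 0.395 with an estimated correlation), and this call was lost without CD 3 (0.491), with the B cell level in the model (0.701) and with the dimmest 50% of genes left out (0.0535). With the B cell level in the model the medians were 0.44 for macrophage, 0.24 for T cell, 0.15 for Th1 and 0.25 for interferon-gamma response genes, and these 4 calls held.

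All 49 cell cycle genes had higher values in CD than in HC, with a median of 0.48 (camera adjusted p = 1.29e-15; adjusted p = 0.351 with an estimated correlation). Rrm2, which makes the building blocks of DNA, had 1.05 ± 0.39, the replication helicase gene Mcm2 0.73 ± 0.27 and Ccna2 0.65 ± 0.27. For 9 members the unadjusted p was under 0.05, and limma called 0 adjusted over the list alone. With a term for sex the median was 0.16 and the call held, and among arrays with low Xist alone it was 0.41. Endothelial genes were higher in 25 of 29 members, with Gpihbp1 of capillaries at 0.98 ± 0.32 and Erg at 0.56 ± 0.20 (median 0.44, camera adjusted p = 1.77e-06; adjusted p = 0.399 with an estimated correlation), a median of 0.24 without HC 2 or without the 4 narrow arrays and 0.14 with the term for sex. With sex and Hoxb13 together the endothelial median was 0.02 and the call was lost. The endothelial list lay at -0.01, -0.57, 0.50 and -0.35 in HC 1 to HC 4. The fibroblast list varied beside it, at 0.24, -0.59, 0.72 and -0.64. Tight junction genes were lower in 23 of 30 members, with occludin (Ocln) at -0.75 ± 0.24 and a median of -0.15 (camera adjusted p = 0.00451; adjusted p = 0.351 with an estimated correlation). Cholesterol synthesis genes were lower in 26 of 33, with Srebf1 at -0.42 ± 0.14 and a median of -0.21 (camera adjusted p = 0.00209; adjusted p = 0.399 with an estimated correlation). This call was lost without HC 2 (0.0619) or without the 4 narrow arrays (0.0812). The chaperone genes Hspa5 (0.44 ± 0.10) and Manf (0.45 ± 0.13) of the endoplasmic reticulum stress list rose adjusted over the list alone. That list had a median of 0.08 (camera adjusted p = 0.025; adjusted p = 0.435 with an estimated correlation) and lost its call without HC 3, HC 4 or CD 3 (up to 0.14), with the term for sex (0.12) and among arrays with low Xist alone (0.147). Camera called 24 of 43 lists, against 0 with an estimated correlation and 0 with fry, where the adjusted p with an estimated correlation was 0.191 to 0.724 for the 24.

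**Figure D4:**
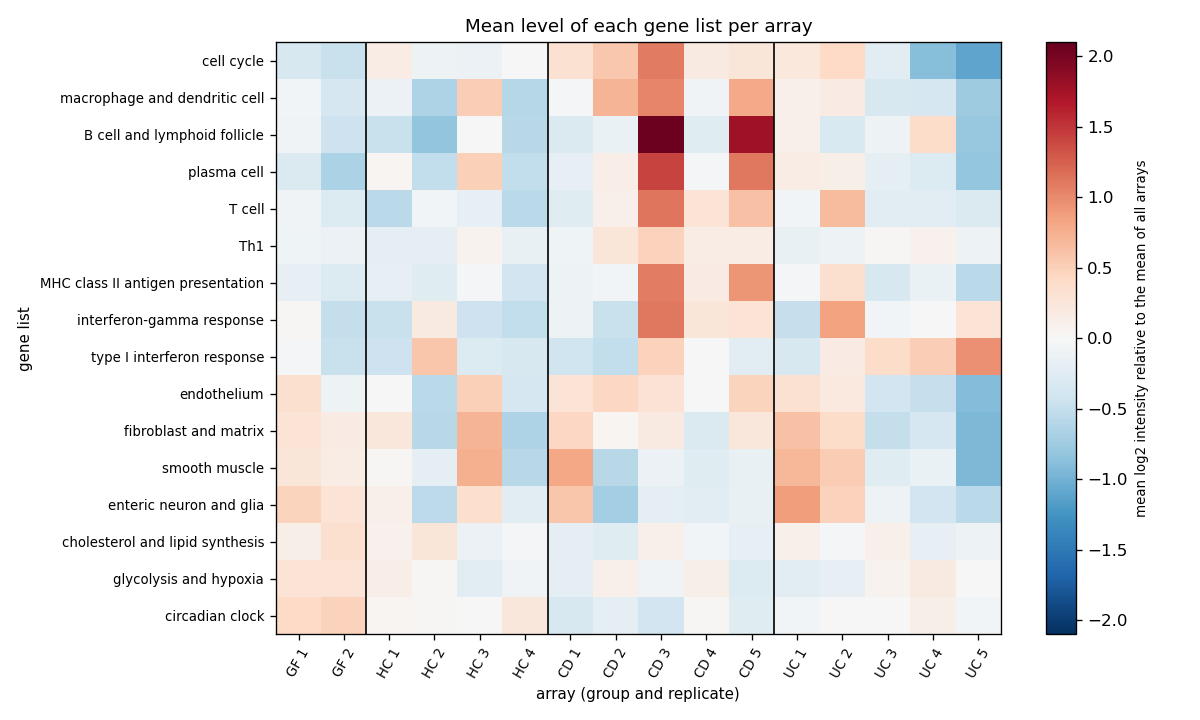
Mean log2 level of 16 gene lists in each of the 16 arrays, relative to the mean of all arrays. The B cell list stands at 2.06 in CD 3 and 1.78 in CD 5, and the type I interferon list at 0.38 to 0.96 in UC 3, UC 4 and UC 5.

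For UC against HC limma called 0 genes, the smallest adjusted p was 0.364 and 1406 genes had an unadjusted p under 0.05. This does not show that the groups are alike. In the simulation 61.2% of log2 changes of 1 were called here. That share is likely too high for the real arrays, since many genes were changed at once in the simulation. The count was 0 with each array left out. With the replicate number as a block it was 1, Sprr1a (limma adjusted p = 0.0122). The arrays did not overlap for 1.8% of genes, against 1.59% by chance. Among genes that did not pass in the main fit, Slc12a3, a sodium chloride cotransporter, was higher by 0.77 ± 0.13 (limma adjusted p = 0.364). Sprr1a, a cornified envelope protein, was at 6.56 ± 0.48 in UC and 5.05 ± 0.31 in HC (1.51 ± 0.30), and Zfp952, Serpind1 and Hs3st2 were higher by 0.63 ± 0.14, 0.70 ± 0.16 and 0.71 ± 0.17. On the lower side were Zfp608 (-0.88 ± 0.20), Cryzl2 (-1.01 ± 0.23), Klhdc7a (-0.67 ± 0.15), Dcaf5 (-0.66 ± 0.15) and Lurap1 (-0.52 ± 0.12), and the limma adjusted p was 0.748 for each of these apart from Slc12a3. None of the 18 genes covered throughout reached an unadjusted p under 0.05 with limma, and Wdfy1 was at 5.55 ± 0.27 in UC and 5.34 ± 0.37 in HC.

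Type I interferon response genes had higher values in UC than in HC in 26 of 31 members, with Cmpk2 at 0.94 ± 0.25 and Ifit1 at 1.87 ± 0.54. The median was 0.46 (camera adjusted p = 4.67e-05; adjusted p = 0.996 with an estimated correlation), 4 members had an unadjusted p under 0.05, and limma called 0 adjusted over the list alone. It was 0.27 without the 4 narrow arrays, 0.25 without UC 5, 0.73 without HC 2 and 0.26 among arrays with low Xist, with the call held. Cell cycle genes were lower in 44 of 49 members, with Cdc20 at -0.70 ± 0.33 and a median of -0.30 (camera adjusted p = 5.37e-05; adjusted p = 0.996 with an estimated correlation). Their mean level was -0.90 in UC 4 and -1.10 in UC 5, the call was lost without either (medians of -0.17 and -0.13, adjusted p up to 0.21), and without UC 2 the median was -0.49. Without the 4 narrow arrays it was 0.28 and among arrays with low Xist 0.24, and the call turned upward, while among arrays with high Xist it was -0.67. Interferon-gamma response genes were higher in 23 of 29 members, with Ubd at 1.30 ± 0.49 and a median of 0.38 (camera adjusted p = 0.000639; adjusted p = 0.996 with an estimated correlation), a call lost without UC 2 (0.207, median 0.11) and among arrays with high Xist alone (0.251, median 0.13), with a median of 0.63 without the narrow arrays. T cell genes were higher in 24 of 26, with Cd7 at 0.85 ± 0.34 and a median of 0.22 (camera adjusted p = 0.00677; adjusted p = 0.996 with an estimated correlation), lost without HC 1 or UC 2 (up to 0.261). The T cell median was 0.09 without UC 2, 0.37 without UC 5, 0.40 without the narrow arrays and 0.49 among arrays with low Xist, and among arrays with high Xist it turned to -0.07 and the call was lost. Camera called 4 of 43 lists, 12 without HC 3, 8 without UC 1 and 7 without HC 2, against 0 with an estimated correlation and 1 with fry.

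CD mice differed from UC mice in 4 genes. Wdfy1 had a log2 fold change of -1.99 ± 0.17 (3.98-fold lower in CD, limma adjusted p = 6.67e-05), and Erdr1 was 2.59 ± 0.28 higher (6.01-fold, limma adjusted p = 0.00116). Alas1, the first enzyme of heme synthesis, was at 6.67 ± 0.09 in CD and 5.98 ± 0.07 in UC (0.69 ± 0.11, limma adjusted p = 0.0446). Zfp429, a KRAB zinc finger protein, was at 4.13 ± 0.99 and 6.52 ± 0.48 (-2.38 ± 0.36, limma adjusted p = 0.0446), with GF at 5.67 ± 0.04 and HC at 6.07 ± 0.15. No CD array overlapped a UC array in the probe sets used for these genes, but in the second probe set of Erdr1 UC 4 (7.55) lay above CD 2 (7.31) and CD 3 (7.50). Zfp429 was at 5.81 in CD 3 and at 3.24 to 4.06 in the other 4 CD arrays, and its neighbour Zfp874a, chosen after its values were seen, had -1.96 ± 0.35 without passing (limma adjusted p = 0.123). Wdfy1 and Erdr1 were called with each array left out, Alas1 in none of these 10 fits (0.0505 to 0.17), and Zfp429 only without CD 3 (0.0534 to 0.194 in the others). Without the 4 narrow arrays, Erdr1 (2.54, adjusted p of 0.0776), Alas1 (0.69, 0.98) and Zfp429 (-2.15, 0.98) lost their calls, with 2 UC arrays left. Over 24 alternatives the log2 fold change ran from 0.62 to 0.72 for Alas1 and from -2.80 to -2.15 for Zfp429. The adjusted p ran from 3.54e-05 to 0.0503 for Wdfy1, from 0.000752 to 0.0776 for Erdr1, from 0.021 to 0.988 for Alas1 and from 7.99e-05 to 0.988 for Zfp429. At an unadjusted p under 0.05 there were 3078 genes, and 1.57% had arrays that did not overlap, against 0.79% by chance. Of the 18 genes covered throughout, Fut2 (0.90 ± 0.22) and Cxcl9 (1.53 ± 0.71) had an unadjusted p under 0.05 and did not pass (limma adjusted p = 0.265 and 0.352).

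All 49 cell cycle genes had higher values in CD than in UC, with a median of 0.82 (camera adjusted p = 3.54e-26; adjusted p = 0.525 with an estimated correlation). Adjusted over the list alone, 40 rose and 9 did not pass, and examples are Birc5 (1.03 ± 0.26), the spindle checkpoint kinase Bub1b (1.18 ± 0.31) and Ccna2 (0.98 ± 0.25). Without the 4 narrow arrays, of which UC holds 3, the median was 0.17, and with a term for sex it was 0.45, with the call held. Macrophage and dendritic cell genes were higher in 32 of 35 members, 6 of them adjusted over the list alone, such as Cd68 (1.58 ± 0.47) and the growth factor receptor Csf1r (1.36 ± 0.42). Their median was 0.73 (camera adjusted p = 4.04e-11; adjusted p = 0.525 with an estimated correlation), and 0.30 without the narrow arrays. B cell genes were higher in 26 of 27 members, with Cxcl13 at 1.56 ± 0.56 and a median of 0.80 (camera adjusted p = 6.65e-07; adjusted p = 0.581 with an estimated correlation), the highest levels again being those of CD 3 and CD 5. The B cell median was 0.41 without CD 3 and 0.51 without CD 5, with the call held. Endothelial genes were higher in 26 of 29, such as Plvap of fenestrated vessels (1.68 ± 0.53), with a median of 0.63 (camera adjusted p = 5.13e-08; adjusted p = 0.525 with an estimated correlation). Without the 4 narrow arrays this median was 0.07 and the call was lost, and with the term for sex it was 0.31. Type I interferon genes were lower in CD in 26 of 31 members, 2 of them adjusted over the list alone, with Cmpk2 at -1.01 ± 0.24 and Irf7 at -1.40 ± 0.36. Their median was -0.45 (camera adjusted p = 0.000928; adjusted p = 0.582 with an estimated correlation), and -0.05 with the call lost without the 4 narrow arrays. It was -0.08 with the term for sex, where the call was also lost, and -0.70 without UC 1. Epithelial stem cell genes were higher in 18 of 23 members, with the stem cell receptor Lgr5 at 0.83 ± 0.32 and a median of 0.32 (camera adjusted p = 0.00382; adjusted p = 0.525 with an estimated correlation), and -0.06 without the narrow arrays. The stem cell call was lost with the term for sex (median 0.06), and the median was 0.20 without UC 5 and 0.49 without UC 2. T cell genes were higher in 23 of 26 (median 0.38, camera adjusted p = 0.00157; adjusted p = 0.581 with an estimated correlation), a call lost without CD 3 (0.105, median 0.20), without the 4 narrow arrays (0.438, median 0.05) and with the B cell level in the model (0.123, median 0.13). Camera called 15 of 43 lists, against 0 with an estimated correlation and 0 with fry.

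For the mean of CD and UC against HC limma called 0 genes, the smallest adjusted p was 0.513 and 1165 genes had an unadjusted p under 0.05. With the replicate number as a block limma called 1, Sprr1a (adjusted p of 0.00382). Sprr1a was higher in both groups, at 6.53 ± 0.65 in CD and 6.56 ± 0.48 in UC against 5.05 ± 0.31 in HC (1.49 ± 0.27, limma adjusted p = 0.513). Klhdc7a had lower values in both (-0.77 ± 0.13, limma adjusted p = 0.513). Slc12a3 (0.51 ± 0.11), Tia1 (0.39 ± 0.09), Spn (0.62 ± 0.14), Erdr1 (1.19 ± 0.26), Wdfy1 (-0.79 ± 0.15), Zfp608 (-0.82 ± 0.18), Ptpru (-0.65 ± 0.14) and Micall2 (-0.65 ± 0.14) did not pass either. The values of Erdr1 and Wdfy1 come from CD. Erdr1 was at 8.99 in CD, 6.41 in UC and 6.50 in HC, and Wdfy1 at 3.55, 5.55 and 5.34. The arrays did not overlap for 0.25% of genes, against 0.2% by chance. Retnlb was the only 1 of the 18 genes covered throughout with an unadjusted p under 0.05 (2.53 ± 1.01, limma adjusted p = 0.923). In CD and in UC against HC, 0 called genes were shared. The log2 fold changes correlated at 0.33 across genes, which are not independent replicates, against 0.57 in shuffled data, and at -0.23 to 0.20 when CD and UC were each set against a different pair of HC arrays.

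T cell genes had higher values in the mean of CD and UC than in HC in 25 of 26 members, with Cd3d at 1.10 ± 0.33 and a median of 0.45 (camera adjusted p = 2.57e-09; adjusted p = 0.517 with an estimated correlation). B cell genes were higher in 26 of 27, with Ltb at 1.18 ± 0.38 and a median of 0.73 (camera adjusted p = 1.31e-09; adjusted p = 0.542 with an estimated correlation), most of it in CD 3 and CD 5. Interferon-gamma response genes were higher in 25 of 29, with Ido1 at 1.38 ± 0.48 and a median of 0.44 (camera adjusted p = 5.01e-07; adjusted p = 0.542 with an estimated correlation). Macrophage and dendritic cell genes were higher in 27 of 35 (median 0.41, camera adjusted p = 3.91e-06; adjusted p = 0.565 with an estimated correlation), a value that comes from CD, as the median was 0.03 in UC against HC (camera adjusted p = 0.996). Th1 genes were higher in 14 of 17, and Stat4 (1.17 ± 0.32) and Il18rap (0.58 ± 0.17) rose adjusted over the list alone. Both genes lie among the dimmest 50%, and the Th1 list was not tested with those left out. The Th1 median was 0.12 (camera adjusted p = 0.000668; adjusted p = 0.517 with an estimated correlation), and the call was lost without the 4 narrow arrays (0.0743). These 5 calls held with each array left out, but in UC against HC only the T cell and interferon-gamma lists of the 5 were called. The interferon-gamma median was 0.29 without HC 1, 0.67 without HC 2, 0.27 without HC 4 and 0.28 without CD 3, the macrophage median 0.26 without HC 2, 0.68 without HC 3 and 0.25 without HC 4, and the Th1 median 0.27 without HC 3. Camera called 20 of 43 lists, but 9 without CD 3, 11 without HC 2, HC 4 or UC 2, and 13 without UC 1, and 0 with an estimated correlation or with fry.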

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

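The tests of splits of the arrays and of the Nnt level were set before their results were seen. The tests of sex, position along the colon, shared origin, follicles, CD 3 and time of day were chosen only after the result was seen.

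Of 213 sets of arrays, each a gene or list within 1 group, 22 held an array far from the others of its group, where chance gives this in about 1 in 20 groups, or 10.7 sets. The value given is the gap to the nearest array divided by the range of the group. In CD, CD 3 stood apart for Il22 (0.887; level 1.59 against 0.29 to 0.44), Lcn2 (0.714; 5.54 against 2.99 to 3.72), Nos2 (0.836; 5.18 against 1.32 to 1.96) and the neutrophil list (0.754), and CD 4 for the nutrient transport list (0.786). In UC, UC 2 stood apart for Cxcl9 (0.712; 7.24 against 3.66 to 4.69) and the T cell list (0.742), UC 1 for Reg3g (0.717; 7.83 against 2.32 to 3.88) and Foxp3 (0.937), UC 3 for Spn (0.728) and UC 5 for Il22 (0.857; 1.63 against 0.35 to 0.53). In HC, HC 3 stood apart for Erdr1 (0.839; 7.59 against 5.98 to 6.24), Hs3st2 (0.879) and the Paneth cell (0.92), oxidative phosphorylation (0.923), Th1 (0.832) and type 2 (0.942) lists. HC 4 stood apart for Wdfy1 (0.832; 4.80 against 5.46 to 5.59) and Angptl4 (0.851), HC 2 for the interferon-gamma (0.877) and type I interferon (0.856) lists and HC 1 for Slc12a3 (0.916).

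The change against GF differed between groups for 4 genes, tested as the difference between the groups. Between CD and HC the log2 difference was -1.79 for Wdfy1 and 2.49 for Erdr1. Between CD and UC it was -1.99 for Wdfy1, 2.59 for Erdr1, 0.69 for Alas1 and -2.38 for Zfp429. For CD against HC, 4 of 100 splits of the arrays gave at least 2 genes, the real split included. This is just under the bound of 5 set first, with no allowance for the other counts tested this way, so chance is not excluded. The highest other split gave 39 genes, several times the real count, which points to a structure of the samples: it sets HC 1, HC 2, HC 4 and CD 4 against the others, and Fxyd4, chosen after its values were seen, was at 9.31 to 10.18 in those 4 arrays and at 1.96 to 3.87 in the other 5. For CD against UC only the real split of 100 reached 4 genes (1 of 100, highest other 3), which argues against chance, again with no such allowance. For UC against HC and for the mean of CD and UC against HC the real count is 0, which all 100 splits reach. The highest other splits gave 1978 and 454 genes, several times the real count, which points to a structure of the samples: the split with 1978 genes sets HC 2, UC 3, UC 4 and UC 5, the arrays with the narrowest spread, against the others.

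Wdfy1 was low and Erdr1 high in every GF and CD array, and the reverse in every HC and UC array, although in the second probe set of Erdr1 UC 4 (7.55) lay above CD 2 (7.31) and CD 3 (7.50). Sex as the whole cause is argued against: with a sex term the CD against HC log2 fold changes were -1.69 for Wdfy1 (limma adjusted p = 0.00828) and 2.59 for Erdr1 (limma adjusted p = 0.0193), although the gap among arrays with low Xist, 0.97 for Wdfy1 and 2.46 for Erdr1, missed for Wdfy1 the bound of 1 set first, and among those arrays, with 2 HC mice left, Wdfy1 did not pass at a log2 fold change of -1.61. Position along the colon is argued against by -1.84 for Wdfy1 and 2.43 for Erdr1 with the Hoxb13 level in the model, although with sex and Hoxb13 together Erdr1 did not pass (2.53, limma adjusted p = 0.0591, over a range of 9.44e-05 to 0.085 in its alternatives), and a C57BL/6 substrain lacking Nnt by a Nnt difference of only 0.33, with overlapping ranges of 4.79 to 5.26 and 4.19 to 5.07. A shared origin of GF and CD mice, in stock or litter, may explain the pattern and cannot be told apart from the groups. In all, 14 genes separated GF and CD from HC and UC completely, where chance gives 3.9. The other pairings gave 12, where chance gives 5.5, and 4, where it gives 3.9. A bound of more genes than in either other pairing was met. However, the 14 include Wdfy1 and Erdr1, which prompted the test, so meeting it decides nothing. A stricter bound added after the counts were seen, more by over the counting error, was not met. Of the 14, Zfp429 lay in GF (mean 5.67) nearer to HC (6.07) than to CD (4.13). An effect of the microbiota that CD mice lack is the biological explanation and stays open, and genotyping stored DNA of the mice would test between them.

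Immune and cell cycle lists were higher in CD than in HC. Among arrays with low Xist all 7 lists kept their call. Their medians were 0.27 to 1.31, against 0.29 to 1.15 in all arrays, which argues against sex as the whole cause. With a term for sex the cell cycle median was 0.16 in place of 0.48. That term rests on HC and UC, where the narrow arrays all have high Xist, and arrays with low Xist alone gave 0.41. All 7 also kept their call without CD 3 (medians 0.19 to 0.76), which argues against CD 3 as the whole cause. CD 3 and CD 5 were not left out together. The B cell list stood at -0.31, -0.14 and -0.25 in CD 1, CD 2 and CD 4 and at -0.83 to -0.01 in HC. Keeping a call is a weak test, since the other splits of the CD and HC arrays gave a median of 15 called lists. The split with 39 genes, which sets HC 3 with the CD arrays other than CD 4, was not put in the model. The macrophage (0.51 in HC 3, -0.08 in CD 4) and B cell (-0.01, -0.25) lists were higher in HC 3 than in CD 4. The cell cycle (-0.12, 0.19), T cell (-0.17, 0.28), interferon-gamma (-0.43, 0.25), Th1 (0.07, 0.16) and MHC class II (-0.02, 0.18) lists were lower there. With the level of Cd79a and Ms4a1 in the model, both the macrophage and dendritic cell list and the cell cycle list kept their call, 2 of 2. Their medians went from 0.86 to 0.44 and from 0.48 to 0.35, which argues only weakly against lymphoid follicles as the whole cause. The MHC class II median went from 0.76 to 0.04, so that follicles in the tissue piece may explain that list. Staining sections for B cells would test this. Chance could not be excluded for the number of lists: 18 of 100 splits gave at least 24 lists (highest other 30), 89 gave at least 4 for UC against HC (highest other 15), 37 gave at least 15 for CD against UC (highest other 23) and 17 gave at least 20 for the mean of CD and UC against HC (highest other 28). An effect of the CD microbiota on these cells stays open as well, and none of the 7 lists was called with an estimated correlation (adjusted p of 0.191 to 0.399).

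The clock genes Dbp, Ciart, Per1 and Nr1d1 were higher in GF than in most colonised mice. Sex as the whole cause is argued against, since for 4 of 4 genes every UC array with high Xist lay below both GF arrays. These UC arrays are all among the 4 narrow arrays, so that test alone cannot set sex apart from narrow spread. For Ciart, Per1 and Nr1d1 every HC array also lay below both GF arrays, among them HC 3, which has high Xist and is not narrow. For Dbp the HC arrays reached 5.92, above the lower GF array (5.73). A different time of day of tissue collection may explain the pattern: it predicts a shift of the opposite arm, and Arntl and Npas2 were 1.49 higher on average in colonised mice than in GF, with Dbp spanning a range of 2.95 within HC alone. An effect of the microbiota on the clock predicts shifts of this kind too and stays open, and sampling both groups at several fixed hours would test between them.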

How the results depend on the processing

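The alternatives with a sex term, arrays of high or low Xist, Hoxb13, the 4 narrow arrays or the B cell level were chosen after seeing the data. No named gene that was called in the main fit or in an alternative changed sign in that alternative. Sign changes of genes called in neither fit were not counted. With each array left out in turn, the named genes gave 6624 results on the same side of the threshold, 52 that lost and 4 that gained a call, and the lists gave 1083, 222 lost and 1 reversed: fibroblast in CD against HC (-0.01 without HC 4; range -0.01 to 0.46 without HC 3). Leave-one-out counts of genes ran from 0 to 1 for HC against GF (main 2), 0 to 5 for CD against GF (1), 0 to 5 for UC against GF (3), 0 to 4 for the 3 groups against GF (1), 2 to 3 for CD against HC (2) and 2 to 4 for CD against UC (4), and were 0 for UC and for the mean of CD and UC against HC. CD against UC gave 2 without any of UC 1, UC 3, UC 4, UC 5, CD 1, CD 2, CD 4 or CD 5, and CD against HC gave 3 without HC 1, HC 3 or CD 3. Counts of lists ran from 7 to 12 for HC against GF (11), 19 to 29 for CD against GF (25), 8 to 17 for UC against GF (9), 10 to 23 for the 3 groups against GF (20), 20 to 27 for CD against HC (24), 3 to 12 for UC against HC (4), 12 to 19 for CD against UC (15) and 9 to 23 for the mean of CD and UC against HC (20). Where a count fell without an array, fewer samples are a cause that the construction gives. For counts that rose without an array the cause was not tested. Where a GF array is left out, the lone GF array is assumed to vary like the other groups.

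Counts of genes moved by more than 1.5 times as follows. Without the dim 50% of genes: 0 for CD and 0 for the 3 groups against GF. With probe sets averaged: 0 for HC against GF and 1 for CD against HC. With every probe set: 0 for HC, 0 for CD, 1 for UC and 0 for the 3 groups against GF, 2 for CD against UC. With a trended, robust variance: 0 for HC and 0 for the 3 groups against GF. With only the groups compared: 0 for HC, 21 for CD and 0 for UC against GF, 1 for CD against HC, 2 for CD against UC. With cyclic loess: 2 for CD against GF and 2 for CD against UC. With array weights: 4, 40, 5 and 28 for HC, CD, UC and the 3 groups against GF. With sex: 0 for HC, 0 for CD and 0 for the 3 groups against GF, 2 for CD against UC. Low Xist alone gave 1 for CD against UC, and high Xist alone 0 for HC and 0 for UC against GF. With Hoxb13: 0 for HC against GF, 2 for CD against UC. With sex and Hoxb13: 0 for HC, 0 for CD, 8 for UC and 0 for the 3 groups against GF, 1 for CD against HC, 2 for CD against UC. Without the narrow arrays: 0 for HC, 6 for CD, 0 for UC and 2 for the 3 groups against GF, 1 for CD against HC, 1 for CD against UC. The replicate numbers were also tried as a block, although of 19 pairs of arrays with 1 number only 4 correlated above 0.1 and 9 were below 0. It gave 0 for HC, 0 for CD, 0 for UC and 0 for the 3 groups against GF, and 1 gene each, Sprr1a, for UC against HC and for the mean of CD and UC against HC.

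Counts of lists moved too. With an estimated correlation they were 1 for CD and 1 for the 3 groups against GF and 0 elsewhere. fry gave 1 for CD, 2 for UC and 1 for the 3 groups against GF, 1 for UC against HC and 0 elsewhere. For the mean of CD and UC against HC, the count was 13 without the dim 50% of genes and 13 with sex. For UC against GF it was 14 with high Xist alone, 19 with Hoxb13, 14 with sex and Hoxb13 and 17 without the narrow arrays. For UC against HC these settings gave 10, 10, 7 and 11, and low Xist alone gave 14. Without the narrow arrays it was 7 for HC and 13 for the 3 groups against GF, with the block 12 for the latter, and with the B cell level 15 for CD against HC and 9 for CD against UC.

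Called lists whose camera direction reversed had these medians. For the 3 groups against GF, B cell (-0.13) with the block, and fibroblast, whose median stayed negative, with the block (-0.05) and without the narrow arrays (-0.02). For CD against GF, endothelium with sex (-0.20) and with sex and Hoxb13 (-0.21). For UC against GF without the narrow arrays, fibroblast (0.27) and endothelium (0.13). For CD against HC, fibroblast with sex (-0.01), Hoxb13 (-0.12), both (-0.23) and the B cell level (-0.04), and plasma cell with the last (-0.13). For UC against HC, cell cycle with low Xist alone (0.24) and without the narrow arrays (0.28), and T cell with high Xist alone (-0.07). For CD against UC, stem cell (-0.06) and fibroblast (-0.33) in both of those first settings, and fibroblast with sex and Hoxb13 (0.06, camera direction down). For the mean of CD and UC against HC, cell cycle with sex (-0.07) and with both (-0.10), and endothelium with Hoxb13 (-0.07) and with both (-0.11). Beyond fewer genes or samples where a setting leaves some out, the cause was not tested. Signal over background cannot be given from the summarised intensities, and the number of arrays limits the precision.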

Other observations

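The tests of lists were set before the data were seen, and only the 2 ion transport genes at the end were chosen after their values were seen. Of the 43 lists, 10 were called in none of the 8 comparisons. Goblet cell and mucin genes (33 measured) came closest in the mean of CD and UC against HC, with a median of -0.07 (camera adjusted p = 0.108), and Muc2, the main mucin of the colon, lay at 10.16 in GF, 10.49 in HC, 10.30 in CD and 10.61 in UC. Absorptive colonocyte genes (36) had a median of -0.22 in CD against HC (camera adjusted p = 0.194). Genes of Th17 cells and interleukin-22 (22) had 0.07 in CD against GF (camera adjusted p = 0.0918), smooth muscle genes (33) -0.29 in the 3 colonised groups against GF (camera adjusted p = 0.0909), and fatty acid oxidation genes (39) 0.14 in CD against UC (camera adjusted p = 0.0697). Adipocyte genes (24) had -0.22 there (camera adjusted p = 0.0697). Xenobiotic metabolism (52), receptors for bile acids and short-chain fatty acids (25), mast cells (18) and distal colon position (8) reached camera adjusted p of 0.253, 0.147, 0.399 and 0.477 at the lowest.

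Mouse orthologues of inflammatory bowel disease risk genes (58 measured) had a median of 0.04 in CD against HC, with 9 members higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0366; adjusted p = 0.351 with an estimated correlation). This call held in 7 of 19 alternatives and was lost without HC 2, HC 4, CD 3 or CD 5, with a camera adjusted p up to 0.185 and a median of 0 without CD 3. Genes of enteroendocrine cells were lower in CD than in GF in 25 of 38 members, with Resp18 of secretory granules at -1.60 ± 0.47 (median -0.19, camera adjusted p = 0.0102; adjusted p = 0.317 with an estimated correlation), and this median was -0.32 without CD 1 and -0.48 with a term for sex. Regulatory T cell genes were higher in CD than in HC in 16 of 20 members, with the integrin Itgae at 1.09 ± 0.37 and Icos at 0.63 ± 0.23 (median 0.22, camera adjusted p = 0.00201; adjusted p = 0.308 with an estimated correlation), and the B cell list was highest in CD 3 and CD 5. Nt5e of this list went the other way (-1.55 ± 0.65). Its members Foxp3 (2.47 ± 0.21 in CD, 2.33 ± 0.25 in HC) and Il10 (1.40 and 1.47) differed little, so the list does not show more regulatory T cells. The regulatory T cell call was lost with the level of Cd79a and Ms4a1 in the model (0.279) and with the dimmest 50% of genes left out (0.0513). Genes of eosinophils and innate lymphoid cells, tested as 1 list, were higher in 14 of 18, with the interleukin-7 receptor Il7r at 1.55 ± 0.46 (median 0.44, camera adjusted p = 0.000101; adjusted p = 0.191 with an estimated correlation). The ion transport genes Fxyd4 and Atp12a varied within groups: Fxyd4 lay at 2.02 to 9.79 in CD and at 2.37 to 10.12 in UC.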
